A study of Homo sapiens with 16 samples.

How the data were processed

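RNA was sequenced from primary lung fibroblasts, the cells that lay down matrix in scarred lung. The cells came from patients with idiopathic pulmonary fibrosis (IPF), a progressive scarring of the lung of unknown cause, or from patients with interstitial lung disease in systemic sclerosis (SSc-ILD), an autoimmune disease of connective tissue. They were kept for 24 h with terazosin, a drug that blocks alpha1-adrenergic receptors, or with vehicle as the control. Per the labels, each of 8 subjects, 4 per disease, gave 1 control and 1 terazosin library, which makes 16 libraries in 4 groups of 4. Libraries were made from poly(A) RNA with a stranded kit.

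The deposited values are raw counts per gene, as whole numbers without normalization, in 1 table of 8 libraries for each disease. Per the submitters' processing notes, the authors used FastQC, STAR 2.7.11a and featureCounts with the GRCh38 (hg38) genome. The annotation release and the strand setting of the counting are not given in the sources used here. The library labels name 1 lane and no batch, and the diseases came in separate tables, so a difference between tables cannot be told apart from a difference between diseases.

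Both tables listed the same 62703 gene identifiers. XIST, genes of the Y chromosome and related genes, 573 identifiers in all, were left out of every table and test, since they report the sex of a person. Of the 62130 identifiers kept, 58264 were placed on the genome with GENCODE release 29. Total counts ran from 13211739 to 26442233 per library. Counting error is small at this depth for all but weakly expressed genes. P-values for single genes measure the spread between these subjects, pooled over both diseases where they share a fit. The pairing named in the labels was checked on the counts: in 8 of 8 pairs, a library's deviations from its group mean correlated with those of its partner, at 0.718 to 0.96, and it resembled its partner more than any library of another subject.

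The following choices were made before the data were examined. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 23417 genes for the 16 libraries and 21586 for the 8 control libraries. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3. All 16 libraries entered 1 fit with the subject as a block. Its contrasts were terazosin minus control in IPF, the same in SSc-ILD, their mean, and their difference (SSc-ILD minus IPF). A separate fit compared SSc-ILD with IPF on the control libraries alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. DESeq2 1.42.0 and limma 3.58.1 (voom) were run on the same designs. Levels are given as CPM, the usual scaling of counts to the same fixed total in every library, with TMM factors.

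There were 32 fixed gene lists: adrenergic receptors; catecholamine synthesis and breakdown; Gq and calcium signalling; immediate early genes; contractile genes; collagens and matrix; collagen processing; matrix breakdown; TGF-beta response; YAP and TAZ targets; inflammatory genes; interferon response; cell cycle; p53 targets; apoptosis regulators; glycolysis; hypoxia; nuclear oxidative phosphorylation genes; mitochondrial genome transcripts; cholesterol synthesis; fatty acid synthesis; endoplasmic reticulum stress; integrated stress response; heat shock; lysosome and autophagy; NRF2 targets; cAMP and CREB targets; alveolar fibroblast genes; adventitial fibroblast genes; nerve growth and axon guidance; circadian clock; and cytosolic ribosomal proteins. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 32 lists of each contrast. Camera asks whether a list moved relative to all other genes. With the preset correlation its p-values treat genes as nearly independent, so they do not measure the spread between subjects. It was repeated with a correlation estimated from the data, which allows for genes that vary together between subjects. The test named fry, in limma, asks whether the genes of a list move 1 way on balance, without comparing them with other genes. Members were also adjusted over their list alone.

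Where a contrast called fewer than 10 genes, the rule for naming genes took all called genes and the 5 with the smallest unadjusted p in each direction. It also took 13 genes fixed in advance for adrenergic receptors, contraction, matrix, IL6 and PGK1, and up to 4 members with the smallest p in each called list. Markers of 8 cell types were fixed as well. Some genes that these rules name are not reported here.

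The alternatives were no subject block, DESeq2 size factors in edgeR, no filter, a filter at 1 CPM, DESeq2, voom, a threshold of 0.1, a fit of each disease alone, terazosin libraries in place of controls for the comparison of diseases, and leaving out each subject or control library. A correction for GC content and transcript length (natural splines with 5 degrees of freedom each, fitted within each subject) was added after the data were seen, alone and with each subject left out. So were exact sign-flip tests of list means over pairs.

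The procedure was tested on simulated counts with known changes. For genes changed 2-fold, edgeR recovered 29 of 49 in the IPF contrast, 35 of 50 in SSc-ILD, 43 of 48 over both diseases, 22 of 49 for the difference and 1 of 47 between diseases. For genes changed 1.5-fold the counts were 21 of 50, 30 of 49, 33 of 48, 9 of 50 and 0 of 47. False calls by edgeR were 5 of 107 calls in IPF, 13 of 127 in SSc-ILD, 13 of 158 over both diseases, 10 of 67 for the difference and 1 of 16 between diseases, against 27 of 72 for DESeq2 between diseases. A contractile list lowered in every simulated IPF subject was called by camera also with an estimated correlation, at an adjusted p of 0.00739. The simulated genes varied independently of each other, so this does not show that such a fall would be called where genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.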

Results

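RNA was measured in lung fibroblasts of 4 subjects with IPF and 4 with SSc-ILD, each with and without terazosin for 24 h. This gave 4 groups of 4 libraries: IPF control, IPF terazosin, SSc-ILD control and SSc-ILD terazosin. The total count per library ran from 21674065 to 24117260 in IPF controls, from 21584491 to 25294211 in IPF with terazosin, from 15052236 to 26442233 in SSc-ILD controls and from 13211739 to 21075483 in SSc-ILD with terazosin. The transcript with the most counts in 16 of 16 libraries was RN7SL1, the RNA of the signal recognition particle, with 1.95% to 3.27% of counts. Transcripts of the mitochondrial genome made up 3.3% ± 0.91 (SD, n = 4) of counts in IPF controls and 3.7% ± 0.66 with terazosin, and 2.24% ± 0.69 in SSc-ILD controls and 2.65% ± 0.76 with terazosin. Genes of cytosolic ribosomal proteins took 1.98% of counts in SSc-ILD control replicate 1, against 1.54% to 1.61% in the other 3 SSc-ILD controls.

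The libraries had the profile of fibroblasts. Of 7 fibroblast markers, 7 passed the filter, with COL1A1, a chain of type I collagen, reaching 12100 CPM. Markers shared by pericytes and smooth muscle passed for 8 of 8 genes, with PDGFRB, a growth factor receptor that fibroblasts also carry, at up to 577 CPM. None of 8 leukocyte markers passed, and the highest, PTPRC, reached 0.763 CPM. For the other cell types, 4 of 7 alveolar epithelial, 4 of 9 airway epithelial, 3 of 7 endothelial, 1 of 6 mesothelial and 2 of 7 nerve markers passed, with highest levels of 13.7 CPM for ABCA3, 7.02 CPM for KRT8, 143 CPM for TEK and 77.1 CPM for KRT7 among the first 4 of these types. Transcripts of the receptors that terazosin blocks were scarce. ADRA1A had 0 counts in 15 of 16 libraries, which allows up to 0.114 to 0.227 CPM at 3 counts, depending on the library. ADRA1B lay between 0.135 and 1.4 CPM and ADRA1D between 0.305 and 4.74 CPM. ADRB1 and ADRB3, beta-adrenergic receptors, had 0 counts in 16 libraries. These ranges run over the 16 libraries, and the limit for ADRA1A covers counting error only.

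The first comparison asked how terazosin altered expression in IPF fibroblasts. Genes of contraction, which give myofibroblasts their pulling force, fell as a group, with all 21 members lower. Their mean log2 change was -0.16 ± 0.088 (SD, n = 4) and lower in 4 of 4 subjects (camera adjusted p = 1.16e-12, adjusted p = 0.375 with an estimated correlation). Among them, ACTG2, a smooth muscle actin, had a log2 change of -0.44 (SE 0.12), TAGLN, which binds actin, -0.34 (SE 0.12), and ACTA2, the actin that marks myofibroblasts, -0.27 (SE 0.11), from 56.0 ± 19.7 to 47.2 ± 19.4 CPM. Collagens and matrix genes fell too, with 29 of 33 members lower, among them THBS1 at -0.20 and FBLN5 at -0.16, and so did genes of collagen processing with 18 of 23 lower, among them LOXL4 at -0.19 (camera adjusted p = 2.85e-05 and 0.0011, adjusted p = 0.375 with an estimated correlation). COL1A1 itself had a log2 change of -0.12, COL1A2 of -0.05, COL3A1 of -0.09 and FN1, fibronectin, of -0.13.

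Inflammatory genes rose in IPF as a group, with 18 of 29 members higher and the mean of the list higher in 2 of 4 subjects (camera adjusted p = 0.00934, adjusted p = 0.375 with an estimated correlation). The chemokines CXCL5, CXCL3 and CXCL1, which draw in neutrophils, had log2 changes of 0.59 (SE 0.13), 0.45 (SE 0.12) and 0.43 (SE 0.12), and PTGS2, the enzyme that starts prostaglandin synthesis, 0.37 (SE 0.11), each higher in 4 of 4 subjects. CXCL5 went from 70.2 ± 47.8 to 118.9 ± 99.4 CPM. The 13 transcripts of the mitochondrial genome, which encode parts of the respiratory chain, rose by a mean log2 change of 0.195 ± 0.295 (SD, n = 4), with 13 of 13 higher, in 3 of 4 subjects (camera adjusted p = 1.23e-06, adjusted p = 0.375 with an estimated correlation). The mean was 0.068 without subject 3 and 0.297 without subject 1, and MT-ATP6 stood at 0.25. Targets of YAP and TAZ, which sense stretch, fell with 21 of 24 lower, among them IGFBP3 at -0.22 and CCN1 at -0.17, interferon response genes with 23 of 28 lower, among them IFITM1 at -0.43, and genes of nerve growth with 20 of 28 lower, among them NTF3 at -0.26. Their camera adjusted p were 0.00138, 0.00434 and 0.00576 (adjusted p = 0.375 with an estimated correlation). Cytosolic ribosomal proteins fell with 27 of 38 lower (camera adjusted p = 0.0422, adjusted p = 0.868 with an estimated correlation).

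Of 23417 genes tested in IPF, edgeR called 1, RN7SL674P (ENSG00000239899.3), a pseudogene copy of the signal recognition particle RNA on chromosome 2 at 11584773 to 11585047 of GRCh38. It rose by a log2 change of 2.00 (SE 0.23, 95% interval 1.5 to 2.5, adjusted p = 0.0152) in 4 of 4 subjects, from 2.59 ± 0.547 to 10.65 ± 3.83 CPM. The IPF controls were the low group, since SSc-ILD libraries held 8.18 ± 3.06 CPM without and 9.59 ± 3.54 CPM with terazosin. DESeq2 and voom each called 1 gene as well. At an unadjusted p under 0.05 there were 431 genes, where unchanged, independent genes would give 1171. Other assignments of the arms within subjects gave up to 382. The count depended on which subjects shared the fit, being 2086 in a fit of IPF alone and 769 in the shared fit without SSc-ILD subject 1. The shared fit pools the spread of both diseases. The SD of log2 changes over genes was 0.129 to 0.195 in IPF subjects and 0.179 to 0.411 in SSc-ILD subjects. P-values in IPF thus carry spread from SSc-ILD. Next by p among genes with a higher value were CXCL5, CXCL3, RABGEF1 and CXCL1, and those with a lower value were led by TUBB2B, a tubulin, at -0.79, ACTG2, OXCT2 at -1.25, LRRC46 at -0.66 and LINC01936 at -0.44, none past the threshold. Among genes named in advance, the log2 change was -0.27 for ADRA1B, -0.37 for ADRA1D, 0.07 for POSTN, -0.12 for CCN2, 0.16 for IL6 and 0.00 for PGK1, each with an adjusted p of 1. Of the members of all lists, 0 passed over all genes and 5 passed when adjusted over the list alone, namely ACTG2 (0.0437) and CXCL5 (0.00836), CXCL3, CXCL1 and PTGS2. EdgeR called 0 genes without IPF subject 1, 2 or 3 or SSc-ILD subject 3, and 0 with the correction for GC content and length, where RN7SL674P had a log2 change of 1.97 and a wider SE of 0.26 (adjusted p = 0.456). List calls ended without IPF subject 1 (inflammatory, interferon and ribosomal, adjusted p = 0.123 to 0.442), subject 2 (ribosomal, 0.0746), subject 3 (collagen processing, mitochondrial and ribosomal, 0.0606 to 0.382) and subject 4 (inflammatory and nerve growth, 0.164 to 0.261), and with the correction for the ribosomal list (0.0698).

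**Figure D1:**
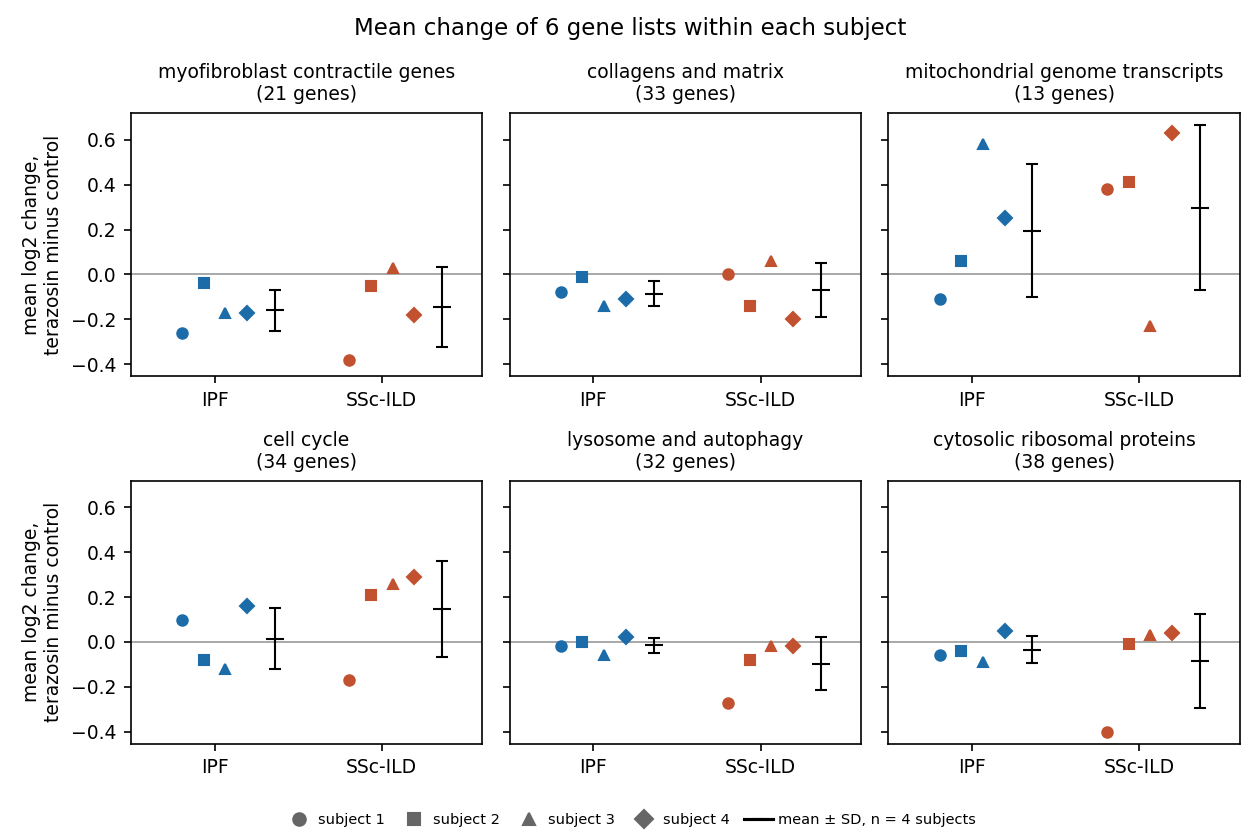
Mean log2 change (terazosin minus control) over the members of 6 gene lists within each subject, with IPF and SSc-ILD side by side; points are subjects, with 1 shape per subject, and the black marks are means ± SD (n = 4). The contractile list lies under 0 in 4 of 4 IPF and 3 of 4 SSc-ILD subjects, and the ribosomal list of SSc-ILD subject 1 lies at -0.404, apart from the others of its disease.

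The second comparison asked the same of SSc-ILD fibroblasts. Cell cycle genes rose as a group, with 28 of 34 higher and a mean log2 change of 0.15 ± 0.216 (SD, n = 4) that was above 0 in 3 of 4 subjects (camera adjusted p = 7.26e-08, adjusted p = 0.313 with an estimated correlation). Without subject 1, whose mean was lower, it was 0.252. CENPE, a motor protein of the kinetochore, had a log2 change of 0.32 (SE 0.08), HMMR, of the mitotic spindle, 0.38, UBE2C, which marks mitotic proteins for breakdown, 0.31, and KIF11, a spindle motor, 0.27. The 13 mitochondrial genome transcripts rose by a mean of 0.30 ± 0.369 with 13 of 13 higher, in 3 of 4 subjects (camera adjusted p = 5.33e-09, adjusted p = 0.313 with an estimated correlation). The mean was 0.473 without subject 3 and 0.186 without subject 4. Among the members were MT-ATP6 at 0.38, MT-ND2 at 0.33 and MT-ND6 at 0.33. Contractile genes fell here too, with 16 of 21 lower and a mean of -0.145 ± 0.18, lower in 3 of 4 subjects (camera adjusted p = 5.84e-05, adjusted p = 0.313 with an estimated correlation). Without subject 1 the mean was -0.066. TNS1, which links actin to adhesion sites, had a log2 change of -0.30, LMOD1, of smooth muscle, -0.26, MYL9, a myosin light chain, -0.30, and ACTA2 -0.31. In subject 1 ACTA2 changed by -0.92 and MYL9 by -0.934, against -0.131 to -0.0368 for MYL9 in the others.

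Collagens and matrix genes fell with 21 of 33 lower and their mean lower in 2 of 4 subjects (THBS2 at -0.47, BGN at -0.27, TNC at -0.28), collagen processing with 18 of 23 lower (PLOD1 at -0.31, P4HA3 at -0.35, PCOLCE at -0.21) and matrix breakdown with 18 of 23 lower (TIMP1 at -0.16). Their camera adjusted p were 0.0043, 0.00214 and 0.0043 (adjusted p = 0.313 with an estimated correlation). COL1A1 stood at 0.19, COL1A2 at 0.03, COL3A1 at 0.08 and FN1 at -0.26. The first 2 varied more between subjects with terazosin. COL1A1 went from 5130 ± 1290 to 6670 ± 4030 CPM and COL1A2 from 7150 ± 605 to 7580 ± 2450 CPM (SD, n = 4). The highest levels over all libraries, 12100 CPM for COL1A1 and 11100 CPM for COL1A2, lay in SSc-ILD with terazosin. By the highest counts of these genes, 164085 and 182037, they came from the smallest library, that of subject 1. FN1 changed by -0.837 in subject 1, against -0.114 to -0.000442 in the others. Genes of lysosomes and autophagy fell with 27 of 32 lower, among them PSAP at -0.27 and the protease CTSA at -0.19, targets of NRF2, which answers oxidative stress, with 15 of 23 lower, and nerve growth genes with 20 of 28 lower. Their camera adjusted p were 0.00022, 0.00214 and 0.0206 (adjusted p = 0.313 with an estimated correlation). HMOX1, which breaks down heme, had a log2 change of -0.45 (SE 0.09), and AKR1C1, a reductase, of -0.28. Alveolar fibroblast genes fell with 14 of 18 lower, among them TCF21, a transcription factor of lung fibroblasts, at -0.23 (camera adjusted p = 0.000872, adjusted p = 0.261 with an estimated correlation). Glycolysis genes fell with 19 of 25 lower, among them GPI at -0.27 (camera adjusted p = 0.00892, adjusted p = 0.498 with an estimated correlation). Targets of cAMP and CREB fell with 15 of 20 lower, among them NR4A2 at -0.22 (camera adjusted p = 0.00953, adjusted p = 0.306 with an estimated correlation). Cytosolic ribosomal proteins fell with 31 of 38 lower, among them RPL3 at -0.25 (camera adjusted p = 0.00214, adjusted p = 0.571 with an estimated correlation). By fry, 2 lists passed, those of alveolar and of adventitial fibroblasts (adjusted p = 0.0259 for both).

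Of 23417 genes, edgeR called 0 in SSc-ILD, with a smallest adjusted p of 0.515 and 1918 genes at an unadjusted p under 0.05; voom called 0 and DESeq2 called 9. Of 8 assignments of the arms within subjects, the real one included, 4 gave 1918 such genes or more, up to 4421. A fit of SSc-ILD alone, which does not pool the spread of IPF subjects, gave 728 such genes. The 9 included MYBL1 (ENSG00000185697.17, chromosome 8, 66562175 to 66614247), a transcription factor related to MYB, at 0.39 (SE 0.08), HELLS, a chromatin remodeller of dividing cells, at 0.40, SKA1, of the kinetochore, at 0.50 and ARHGAP11A at 0.48, each higher in 4 of 4 subjects. They also included HMOX1, RASL12 at -0.42 and PAPPA, a protease that frees insulin-like growth factors, at -0.40. Another, MTND2P28, a nuclear copy of a mitochondrial gene, was chosen after its values were seen (DESeq2 log2 change 0.54). Also among the lowest p were RTL9 at -1.56 and MFAP4, of elastic fibres, at -0.38. Genes named in advance gave -0.10 for POSTN, 0.05 for CCN2, 0.15 for IL6, -0.02 for PGK1, 0.05 for ADRA1B and 0.16 for ADRA1D. Of all list members, 0 passed over all genes and 18 passed when adjusted over the list alone. Among these were CENPE, HMMR, UBE2C and KIF11 of the cell cycle, MT-ND2, MT-ND6, MT-ND4L and MT-ATP6, TNS1 (0.0418), HMOX1 (0.0021), AKR1C1 and AKR1C3 of the NRF2 targets, and CXCL5, ICAM1, XPC, BMF and HSPE1, the last 5 from lists that camera did not call and chosen after their values were seen. Without SSc-ILD subject 1, 8 of the 13 list calls ended, at adjusted p = 0.0682 (matrix breakdown) to 0.967 (glycolysis), the contractile (0.105), lysosome (0.105), NRF2 (0.13), collagen processing (0.13), nerve growth (0.176) and ribosomal (0.402, with its direction turned) lists among them. Collagens and matrix lost its call without subject 2 (0.0852), without subject 4 (0.127) and with the correction for GC content and length (0.0675), which also ended the call of glycolysis (0.364).

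**Figure D2:**
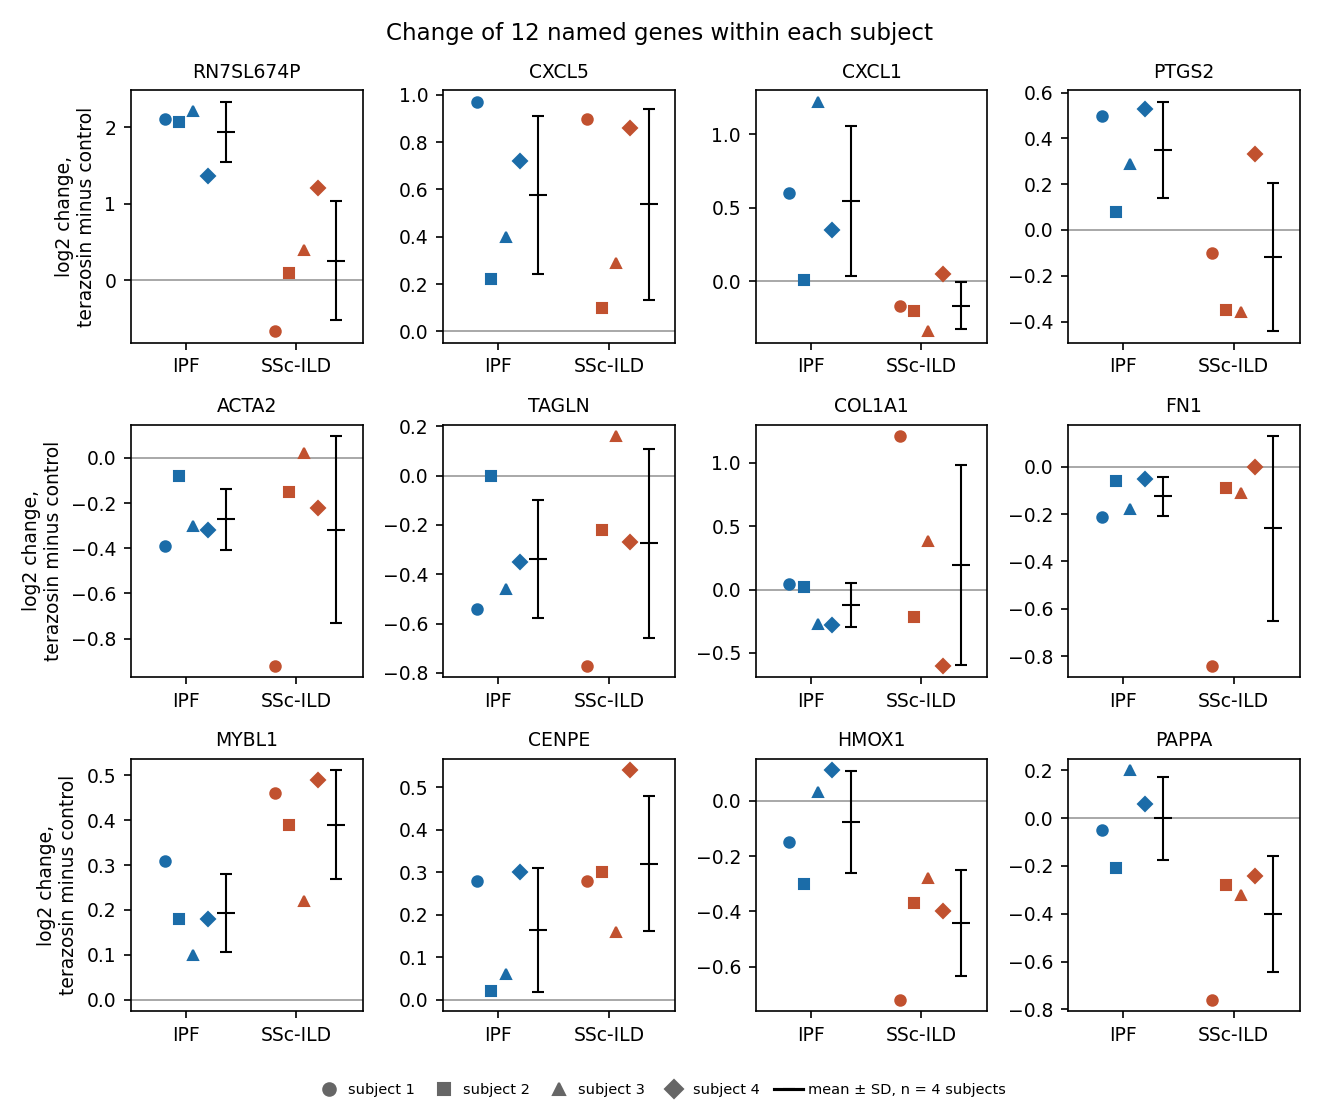
Log2 change (terazosin minus control) of 12 genes within each subject, with IPF and SSc-ILD side by side and a separate scale for each gene; points are subjects and black marks are means ± SD (n = 4). ACTA2 lies under 0 in 4 of 4 IPF and 3 of 4 SSc-ILD subjects, CXCL5 lies above 0 in 8 of 8 subjects, and FN1 of SSc-ILD subject 1 lies at -0.837.

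Over both diseases together, contractile genes fell with 20 of 21 members lower. The mean log2 change was -0.15 ± 0.131 (SD, n = 8), lower in 7 of 8 subjects (camera adjusted p = 1.71e-11, adjusted p = 0.268 with an estimated correlation). An exact two-sided sign-flip test of the subjects' means gave p = 0.0156, adjusted over the 32 lists 0.187; 8 pairs allow 0.00781 at the lowest. The mitochondrial genome transcripts rose with 13 of 13 higher, in 6 of 8 subjects (camera adjusted p = 1.3e-11, adjusted p = 0.268 with an estimated correlation). Cell cycle genes rose with 27 of 34 higher and the mean of the list higher in 5 of 8 subjects, among them CENPE at 0.24 (camera adjusted p = 3.01e-05, adjusted p = 0.498 with an estimated correlation). In IPF alone the mean log2 change of this list was 0.017 ± 0.139 (SD, n = 4). Collagens and matrix genes (28 of 33 lower), collagen processing (18 of 23), matrix breakdown (18 of 23), nerve growth (21 of 28) and alveolar fibroblast genes (14 of 18) fell, at camera adjusted p = 3.01e-05, 8.5e-05, 0.00203, 0.00184 and 0.00152 (adjusted p = 0.268 with an estimated correlation). Ribosomal proteins (29 of 38 lower; camera adjusted p = 0.000985, adjusted p = 0.502 with an estimated correlation), lysosome genes (25 of 32; 0.00132, adjusted p = 0.432 with an estimated correlation) and glycolysis genes (19 of 25; 0.00681, adjusted p = 0.498 with an estimated correlation) fell as well. Without SSc-ILD subject 1 the mean log2 change went from -0.062 to -0.014 for ribosomal proteins and from -0.057 to -0.026 for lysosome genes. It went from -0.061 to -0.022 for glycolysis genes and from -0.072 to -0.044 for collagen processing. By fry, the alveolar and adventitial fibroblast lists passed (adjusted p = 0.0352 for both).

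Single genes over both diseases did not pass edgeR, which called 0 of 23417 with a smallest adjusted p of 0.14 and 2024 genes at an unadjusted p under 0.05; voom called 0. Of 100 assignments of the arms, 15 gave 2024 such genes or more, up to 3787. DESeq2 called 4, RN7SL674P, CXCL5, MYBL1 and MTND2P28. In edgeR, RN7SL674P had a log2 change of 1.12 (SE 0.16, 7 of 8 subjects, adjusted p = 0.14), CXCL5 of 0.59 (8 of 8, 0.155), MYBL1 of 0.29 (8 of 8, 0.303) and MTND2P28 of 0.42 (7 of 8, 0.483). Genes with the smallest p among those with lower values were ARHGDIB at -0.51, ICAM1, an adhesion molecule for leukocytes, at -0.36, THBS4 at -0.98, XPC, which recognises DNA damage, at -0.27 and RASL12 at -0.26. ACTA2 stood at -0.29 (lower in 7 of 8), TAGLN at -0.30 and FN1 at -0.19. COL1A1 stood at 0.03, the mean of opposite signs in IPF (-0.12) and SSc-ILD (0.19). The SSc-ILD value includes the high terazosin library of subject 1. When adjusted over the list alone 31 members passed, 9 contractile (led by TNS1, LMOD1, ACTG2 and TAGLN), 9 mitochondrial, 6 of the cell cycle, NRP2 of nerve growth, and 6 from lists not called, which were CXCL5, ICAM1, XPC, HMOX1, HSPE1 and MSMO1; 0 passed over all genes. HSPE1, a mitochondrial chaperone, and MSMO1, of cholesterol synthesis, were chosen after their values were seen. Glycolysis lost its call without IPF subject 3 (adjusted p = 0.0768), without SSc-ILD subject 1 (0.245) and with the correction for GC content and length (0.448). Ribosomal proteins lost theirs without SSc-ILD subject 1 (0.316).

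The other 21 lists were not called over both diseases by camera, which does not show that they stayed unchanged. Those closest to the drug's receptors gave adjusted p = 0.457 for adrenergic receptors, 0.145 for catecholamine genes, 0.244 for Gq and calcium signalling, 0.244 for immediate early genes and 0.104 for cAMP and CREB targets. Fibrosis and inflammation lists gave 0.12 for the TGF-beta response, 0.253 for YAP and TAZ targets, 0.244 for inflammatory genes, 0.0984 for the interferon response and 0.0672 for adventitial fibroblast genes. For cell fate and stress, p53 targets gave 0.293, apoptosis 0.993, hypoxia 0.124, endoplasmic reticulum stress 0.457, the integrated stress response 0.435, heat shock 0.993 and NRF2 targets 0.0628. Nuclear oxidative phosphorylation genes gave 0.244, cholesterol synthesis 0.696, fatty acid synthesis 0.151 and the circadian clock 0.254. Of these, 11 lists were called by camera in 0 comparisons: adrenergic receptors, catecholamine genes, Gq signalling, TGF-beta response, p53, apoptosis, hypoxia, cholesterol, fatty acids, integrated stress response and adventitial genes, the last of which fry called in SSc-ILD and over both diseases. The changes within subjects followed the GC content of genes. Across 12068 genes, which are not independent replicates, Spearman's rho between log2 change and GC content was -0.01, -0.38, -0.59 and -0.33 in IPF subjects 1 to 4 and -0.05, -0.53, 0.54 and -0.80 in SSc-ILD subjects 1 to 4. With the correction for GC content and length, camera called the contractile list in IPF (2.54e-11, adjusted p = 0.325 with an estimated correlation), in SSc-ILD (0.0182, adjusted p = 0.542 with an estimated correlation) and over both diseases (3.05e-08, adjusted p = 0.199 with an estimated correlation). In SSc-ILD the mean log2 change of the list went from -0.145 ± 0.18 to -0.082 ± 0.121 (SD, n = 4) with this correction, and without subject 1 from -0.066 to -0.022.

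The fourth comparison asked whether the response to terazosin differed between the diseases, as the SSc-ILD minus the IPF change. Cell cycle genes responded more in the upward direction in SSc-ILD, with 30 of 34 members higher (camera adjusted p = 2.01e-05, adjusted p = 0.749 with an estimated correlation). So did YAP and TAZ targets, with 20 of 24 higher (camera adjusted p = 0.00611, adjusted p = 0.749 with an estimated correlation). NRF2 targets (18 of 23 lower), lysosome genes (30 of 32 lower) and inflammatory genes (21 of 29 lower) went the other way, at camera adjusted p = 0.00531, 0.0141 and 0.0462 (adjusted p = 0.749 with an estimated correlation), as did cAMP and CREB targets with 16 of 20 lower (camera adjusted p = 0.0291, adjusted p = 0.679 with an estimated correlation). CXCL1 had a difference of -0.58, CXCL3 of -0.53 and HMOX1 of -0.37, while PKN3, a protein kinase, had 0.56. EdgeR called 0 of 23417 genes (smallest adjusted p = 1, 448 at an unadjusted p under 0.05, a count met by 30 of 35 groupings of the subjects), voom called 0 and DESeq2 called 1, RN7SL674P, at -1.72. Of all list members, 0 passed over all genes and 0 when adjusted over the list alone. The cell cycle call held in 8 of 8 fits without 1 subject, and each of the other 5 lists lost its call in at least 1. These calls used the preset correlation, so they do not measure the spread between subjects. The mean cell cycle changes of subjects overlapped, at -0.12 to 0.16 in IPF and -0.17 to 0.29 in SSc-ILD. Calls ended without IPF subject 1 (3 lists, adjusted p = 0.0517 to 0.72), IPF subject 2 (lysosome, 0.104), IPF subject 4 (4 lists, 0.0902 to 0.361), SSc-ILD subject 1 (4 lists, 0.104 to 0.632), subject 2 (inflammatory, 0.273), subject 3 (3 lists, 0.05 to 0.112) and subject 4 (cAMP, 0.109).

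The fifth comparison set SSc-ILD against IPF fibroblasts without drug. Immediate early genes, which cells switch on within minutes of a stimulus, were higher in SSc-ILD for 20 of 26 members, and targets of cAMP and CREB for 17 of 19 (camera adjusted p = 3.41e-06 and 1.58e-06, adjusted p = 0.468 with an estimated correlation). EGR1, a transcription factor of this class, had 35.4 ± 15.4 CPM in IPF and 118.7 ± 17.6 CPM in SSc-ILD (n = 4 each; log2 difference 1.76), and FOS had 2.26 and 12.6 CPM (log2 difference 2.49). Circadian clock genes were higher for 13 of 17 members, among them PER1 at 0.81 and PER2 at 0.69 (camera adjusted p = 0.00433, adjusted p = 0.468 with an estimated correlation). Lower in SSc-ILD were the mitochondrial genome transcripts with 13 of 13 members, among them MT-CO1 at -0.65 (camera adjusted p = 1.32e-07, adjusted p = 0.628 with an estimated correlation), and ribosomal proteins with 37 of 38, among them RPS18 at -0.47 (camera adjusted p = 7.75e-07, adjusted p = 0.703 with an estimated correlation). Also lower were heat shock genes with 20 of 21 members, among them the chaperone HSPE1 at -0.87, and nuclear oxidative phosphorylation genes with 32 of 38, among them SDHC at -0.39 (camera adjusted p = 5.63e-05 and 7.06e-05, adjusted p = 0.649 with an estimated correlation). Endoplasmic reticulum stress genes were lower for 18 of 20 members, among them the chaperone HSPA5 at -0.65 (camera adjusted p = 0.00308, adjusted p = 0.704 with an estimated correlation). Cell cycle genes were lower for 33 of 34, among them PCNA at -0.37 (camera adjusted p = 0.00658, adjusted p = 0.706 with an estimated correlation).

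Of 21586 genes tested between the controls, edgeR called 0 (smallest adjusted p = 0.115, 1687 at an unadjusted p under 0.05, a count met by 5 of 35 groupings, up to 3866), voom called 0 and DESeq2 called 145, of which 44 were lower in SSc-ILD. In simulated data DESeq2 made 27 false calls among 72 in this comparison. Genes with the smallest p in edgeR were CNNM1, linked to magnesium transport, at 3.59, NPIPB15 at 4.97, CELF2-AS1 at 2.7, CELF2-AS2 at 3.98 and ADAMTS3, which trims procollagen, at 2.44. With lower values in SSc-ILD came MOSPD2 at -0.80, EFNA5, a guidance ligand, at -0.91, MIR503HG at -1.22, MID1 at -0.89 and SKP2, which drives cells into S phase, at -0.70. ACTA2 had 56.0 ± 19.7 CPM in IPF and 121.8 ± 66.7 in SSc-ILD (log2 difference 1.14, adjusted p = 0.594), POSTN a log2 difference of -1.59, IL6 of 1.38, COL1A1 of 0.33, ADRA1B of -0.40 and ADRA1D of -1.23. Of list members, 0 passed over all genes and 16 passed when adjusted over the list alone, with a gene counted in each of its lists. Among them were EGR1 (0.00703), FOS, EGR3 and JUNB of the immediate early genes, FOS, PER1, PDE10A and CRTC1 of the cAMP targets, and PER1 of the clock (0.0389). Cell cycle lost its call without IPF control replicate 2 (adjusted p = 0.511) or 3 (0.595) or SSc-ILD control replicate 4 (0.645), endoplasmic reticulum stress without IPF control replicate 3 (0.0707) and the circadian clock without SSc-ILD control replicate 1 (0.0702). The diseases came in separate tables with separate subjects, so disease and any difference between the tables could not be separated.

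The sign of a list's median, its mean and its camera test differed in 0 of the 48 called results. Among results not called they differed for p53, NRF2 and cAMP targets in IPF, for TGF-beta, inflammatory, interferon, cholesterol and heat shock genes in SSc-ILD, and for apoptosis, cholesterol and heat shock genes over both diseases. They also differed for TGF-beta and nerve growth genes in the difference between diseases, and for adrenergic receptors and interferon, integrated stress response, lysosome, NRF2 and alveolar fibroblast genes between the controls. Camera called 1 list upward in both IPF and SSc-ILD, the mitochondrial genome transcripts, and 5 downward in both. With an estimated correlation it called 0 lists in either disease. With the correction for GC content and length, the mean log2 change of the mitochondrial list went from 0.195 to 0.139 in IPF (0.034 without subject 3) and from 0.298 to 0.229 in SSc-ILD. Camera at the preset correlation still called it (adjusted p = 3.31e-05 and 5.49e-08). In SSc-ILD the subject whose mean fell, subject 3, was also the one with the opposite GC trend (rho 0.54).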

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

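The tests of a shared response, of the GC and length trends in SSc-ILD subject 1 and in the cell cycle list, of a library of another subject and of a response of SSc-ILD fibroblasts were chosen after the results were seen. The test of gene types against GC content and both tests with thinned libraries were written down before their results were seen. The bound for a shared response was changed with the values known, from at least 1 to more than 1 subject of opposite sign; by the first bound that explanation was excluded.

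Among 222 groups of 4 values from the libraries and from lists and genes of the report, 15 held 1 value far from the other 3 by Dixon's ratio (the gap to the nearest value over the whole range), where about 1 in 20 groups, or 11.1, does so by chance. In 9 of the 15 the value apart came from SSc-ILD subject 1. Its control library had 1.98% of counts in ribosomal protein genes against 1.54% to 1.61% in the other controls (ratio 0.841), and its ribosomal list changed by -0.404 on the log2 scale against -0.0147 to 0.0379 (0.881). RPS18, a ribosomal protein gene, had a log2 CPM of 8.51 in that control library against 7.85 in the others (0.996). The other log2 changes of this subject that stood apart were ACTG2 at -0.568 (0.919), FN1 at -0.837 (0.865), MYL9 at -0.934 (0.895), PAPPA at -0.759 (0.86), TCF21 at -0.536 (0.866) and TNC at -0.784 (0.888). In SSc-ILD subject 3, MT-ND2 changed by -0.194 against 0.474 to 0.567 in the others (0.878). THBS1 changed by 0.00767 in IPF subject 2 against -0.288 to -0.259 (0.903). Among IPF controls, replicate 1 stood apart for EFNA5 (0.83), EGR3 (0.889) and MT-ND6, at a log2 CPM of 10.4 against 9.66 to 9.69 (0.955), and replicate 4 for HSPE1, at 3.73 against 4.51 to 4.63 (0.874). The responses of 6 lists differed between the diseases by camera, the cell cycle (adjusted p = 2.01e-05), NRF2 targets (0.00531), YAP and TAZ targets (0.00611), lysosome genes (0.0141), cAMP and CREB targets (0.0291) and inflammatory genes (0.0462), with 0 called under an estimated correlation. Among 136 genes named by the rule or in the report, 5 moved opposite ways in every subject of the 2 diseases, where 0.781% do by chance if directions are even. The mean within-subject change in SSc-ILD minus that in IPF was 0.52 for PKN3, 1.58 for MIF4GD-DT, -2.11 for NDUFB4P6 and -0.73 for DPP3-DT, all 4 of which the rule took for a small p in this difference, and -0.37 for SLIT2, a guidance cue for axons. EdgeR gave each an adjusted p of 1 for the difference.

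In 6 of 8 subjects the log2 changes between the 2 libraries followed GC content, with rho from -0.80 to 0.54 (mean over 8 subjects -0.27, exact two-sided sign-flip p = 0.109). Depth is argued against, since with all libraries thinned to the smallest total the largest absolute rho stayed at 0.79. In 6 of the 6 subjects with an absolute rho above 0.3, protein-coding and long non-coding genes followed GC content with the same sign. A GC bias of single libraries may account for the pattern. A response that follows GC content would give the same signs, so this test does not separate them. A response shared by all subjects stays open, since the sign opposite to the mean rests on 1 subject (rho 0.54), which such a bias could also give, and a response that differs between subjects was not tested.

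SSc-ILD subject 1 changed more than the others, with a standard deviation of log2 changes 2.28 times the median of the other 7 subjects and 280 genes over 2-fold, against 1 to 37. Its control library held 26442233 counts and its terazosin library 13211739, yet with thinned libraries the ratio stayed at 2.11, and with the GC and length trends removed it was 2.34, so neither accounts for it. A library of another subject is argued against, since its 2 libraries correlated at 0.974 with each other, 0.045 above the highest correlation with any other subject. A difference in handling or RNA between these libraries may be the source; the labels give no batch, so this cannot be tested. A stronger response of this subject's cells stays open as well, untested.

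Cell cycle genes rose in SSc-ILD by a mean of 0.15 ± 0.22 (SD, n = 4; 0.252 without subject 1; exact two-sided p = 0.25, where 4 pairs allow 0.125 at the lowest). GC content and length are argued against as the whole cause, since with these trends removed the mean was 0.14 ± 0.18 (0.231 without subject 1) and camera called the list (1.44e-11, adjusted p = 0.308 with an estimated correlation). A response of SSc-ILD fibroblasts may underlie the pattern, but 3 of 4 subjects were higher and subject 1 was not, which with 4 subjects cannot be told apart from variation between cultures.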

How the results depend on the processing

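The correction for GC content and length, alone and with subjects left out, was chosen after the data were seen; the other alternatives were planned. The counts of genes changed by terazosin, 1 in IPF and 0 in SSc-ILD, over both diseases and for the difference, became 6, 57, 46 and 8 without a filter, and the count between controls, 0, became 6. DESeq2 gave 1, 9, 4, 1 and 145. In IPF, 0 were called without the subject block or with the correction, and 5 in a fit of IPF alone (RN7SL674P, PTGS2, PDK4, GK and ADAMTS8, chosen after their values were seen). The count between diseases in terazosin libraries was 1, NPIPB15. DESeq2 size factors, a 1 CPM filter, voom and a threshold of 0.1 kept each count. Leaving out 1 subject or control, with or without the correction, gave 0 to 1 genes in IPF, 0 to 109 in SSc-ILD, 0 to 45 over both, 0 to 3 for the difference and 0 to 1 between controls. The 109, 45 and 3 came without SSc-ILD subject 1 with the correction; the next highest counts were 2, 2 and 1. Uncorrected, IPF dropped to 0 without IPF subject 1, 2 or 3 or SSc-ILD subject 3; corrected, it was 0 with every subject and without any 1 of them except SSc-ILD subject 1 or 4, where it was 1. Single genes were called in SSc-ILD without IPF subject 1 or 4 (RNA5-8SN1), and between controls without IPF control 4 (SPON1) or SSc-ILD control 1 (DYSF) or 2 (ERAP2), each chosen after its values were seen. Of 48 list calls (9, 13, 11, 6 and 9), 0 held with an estimated correlation (0 in each comparison) and 2 by fry, which called 4 lists in all (0, 2, 2, 0 and 0). Without the block 2, 2, 4 and 0 lists were called in IPF, SSc-ILD, both and the difference. DESeq2 size factors kept 47 of 48. The correction kept 35 of 39, ending the ribosomal list in IPF (0.0698), collagens and matrix in SSc-ILD (0.0675) and glycolysis in SSc-ILD (0.364) and over both (0.448). Leaving out 1 subject or control kept 340 of 384 list values, with 43 lost and 1 turned; with the correction, 61 of 312 were lost and 3 turned. List counts then ran from 5 to 11 in IPF, 8 to 14 in SSc-ILD and 2 to 7 for the difference, the lowest without IPF subject 1 (5, corrected), SSc-ILD subject 1 (8) and IPF subject 4 (2). The directions that turned, all without SSc-ILD subject 1, were those of ribosomal proteins in SSc-ILD (adjusted p over all leave-outs 8.51e-05 to 0.464) and glycolysis in SSc-ILD (0.000919 to 0.967) and over both (0.000871 to 0.878). For named genes, log2 changes stayed within 1 SD between subjects and kept their call in 289 of 289 values with DESeq2 size factors. So did 232 of 233 without the block, 122 of 124 in separate fits, 228 of 233 with the correction and 262 of 289 with DESeq2, where 27 were newly called. This bound is loose, since a small change can turn its sign within it. Signs turned in 3, 4, 1, 6 and 3 of these values, in the same order. They turned in 13 and 18 of 289 at the lowest and highest leave-one-out values. The cause was not tested, but the shared fit pools diseases whose spread differed. Fewer subjects give a weaker test, yet leaving out 1 subject gave fewer genes in some uncorrected fits and more in others. At an unadjusted p under 0.05, the 431 genes in IPF became 300 without IPF subject 3 and 769 without SSc-ILD subject 1. The 1918 in SSc-ILD became 1503 without IPF subject 2 and 3440 without SSc-ILD subject 3. Depth limits weak genes most: ADRA1A could be excluded only above 0.114 to 0.227 CPM. The median half-width of the 95% interval of a log2 change above 4 CPM was 0.204 in IPF, 0.207 in SSc-ILD, 0.145 over both, 0.291 for the difference and 0.457 between controls.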

Other observations

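The response correlation, the corrected fits without 1 subject and the splits of the main counts were chosen after the results were seen; the splits of the corrected fit without SSc-ILD subject 1 were written down before.

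Without SSc-ILD subject 1 and with the correction for GC content and length, edgeR called 109 genes in the other 3 SSc-ILD subjects, 85 higher and 24 lower with terazosin. Those that were higher included 14 of the 34 cell cycle members, but these are the 3 subjects whose mean of that list was higher, so this restates the pattern described above. The following genes were chosen after their values were seen. MKI67, a marker of dividing cells, had a log2 change of 0.32 (SE 0.055), CCNA2, cyclin A2, of 0.30 (SE 0.051) and IQGAP3, a scaffold protein of dividing cells, of 0.41 (SE 0.049). Lower were IL1R1, the receptor of interleukin-1, at -0.22, FGF10, a growth factor for lung epithelium, at -0.24 and DCN, the matrix proteoglycan decorin, at -0.21. In subject 1 itself 27 of the 85 were higher and 18 of the 24 lower, with MKI67 at -0.72. With every subject, edgeR called 0 genes, and the other 7 leave-outs with the correction called 0 to 2. A hypothesis is that terazosin may raise proliferation in SSc-ILD fibroblasts; over all 4 subjects the cell cycle list was higher in 3 (exact two-sided p = 0.25), which leaves it open, and no independent samples were at hand to test it. The 3 pairs do not test it, since the subject left out is the one that goes against it. Of the 4 splits of these pairs 1 gave as many genes (real 109, highest other 39), too few for a share under 0.05.

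Contractile genes were lower in 7 of 8 subjects, by a mean of -0.15 and by -0.11 with the correction, with an exact two-sided sign-flip p of 0.0156 for each, 0.187 for the first when adjusted over the 32 lists. Camera gave adjusted p = 0.268 with an estimated correlation, and 0.199 with the correction. Across 12262 genes, which are not independent replicates, the mean responses of IPF and SSc-ILD correlated at r = 0.466 without the correction. The mean rho with GC content was negative in both diseases (-0.33 in IPF, -0.21 in SSc-ILD). A shared GC trend could thus contribute to r, which was not computed with the correction. Of 64 ways to swap drug and control within subjects, 4 gave an r as far from 0 (exact p = 0.0625), up to 0.557 otherwise.

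Arms were also reassigned within subjects, and diseases among subjects, to see how often splits gave counts as large. For genes in IPF, 1 of 8 assignments called as many (real 1, highest other 0), and for lists 2 of 8 (real 9, highest other 9). In SSc-ILD, 1 of 8 did for lists (real 13, highest other 10). With 8 assignments there are too few for a share under 0.05. For lists chance could not be excluded over both diseases, with 15 of 100 assignments (real 11, highest other 14), for the difference between diseases, with 17 of 35 regroupings (real 6, highest other 14), or between controls, with 21 of 35 (real 9, highest other 19). For genes the real count was 0 in the other 4 comparisons, so every split meets it (8 of 8 in SSc-ILD, 100 of 100 over both, 35 of 35 for the difference and 35 of 35 between controls) and the test decides nothing there. The highest counts of the other splits were 692, 383, 1 and 4. The 692 genes arose with the arms of SSc-ILD subjects 2 and 4 swapped and point, like the 383, to a structure of the samples. Its source was not identified: libraries or responses that differ between subjects would both give it, and GC content alone is not shown to. Swapping SSc-ILD subject 3 aligned the GC trends as closely (mean rho -0.48 against 0.46) and called 0 genes. These 2 splits differ only in how subject 1 is aligned with the others. Its trend is hardly captured by rho (-0.05), so this comparison does not decide on GC content. Over both diseases the 3 splits at least as aligned as that with 383 genes (absolute mean rho 0.39) called at most 1. The size of the mean rho did track the count of genes at an unadjusted p under 0.05 over the 100 assignments (Spearman's rho 0.69).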
